A study of Mus musculus with 4 samples.

How the data were processed

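RNA from 2 mouse tumor cell lines was measured on 4 Agilent whole mouse genome expression arrays of 1 slide, with 1 array each for AB1-HA and LLC cells cultured with vehicle or IFN-γ for 24 h. Per the labels' protocols, total RNA was purified on columns and labelled with Cy3, so each array has a single colour. The deposited intensity values are scanner output: per the file headers, Agilent Feature Extraction 10.7.1.1 subtracted the background from each spot, and its processed signal was not normalized between arrays. The series' value table holds log2 values deposited by the authors; how it was made is not given in the sources used here. Set against the scanner signals, its columns had correlations of 0.999 with log2 signals scaled to each array's 75th percentile and centred per probe on the median of the 4 arrays, and its direction was that of the signal. Its column medians were 0.11 and −0.08 for AB1-HA (vehicle, IFN-γ) and −0.13 and 0.08 for LLC. Whether RNA of several cultures was pooled is not given in the sources used here.

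From the processed intensity, log2 values were taken relative to each array's 75th percentile over gene probes. Control spots and spots with non-uniformity or population outlier marks were left out (166 to 201 per array), and the spots of a probe were averaged. A probe counted as well above background on an array where at least 0.5 of its kept spots carried the scanner's mark. The files hold no gene symbols, so each probe's accession was matched without its version to a RefSeq gene table of assembly GRCm38.p6, used for names only since the array annotation is of another build. This named 26581 of 39429 probes for 20140 genes, and 12848 probes stayed unnamed and out of all gene counts. For the 5370 genes with several named probes, the probe with the highest mean over the 4 arrays was used; probes of 1 gene were at least 2-fold apart in opposite directions for 0 genes in AB1-HA, 1 in LLC and 20 between the vehicle arrays, and their differences were at least 2-fold apart for 37, 72 and 590 genes.

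Each comparison is a difference of 2 arrays, and the comparison of the lines' IFN-γ effects is a difference of those differences over the genes well above background on all 4 arrays. Without replicates, no test was run and no p-value is given. A gene not well above background on 1 of the 2 arrays was given a bound against the higher of its own signal there and the lowest signal of a probe well above background on that array (7.01 to 8.26 intensity units, where the 75th percentiles were 1380 to 1598). A gene not well above background on both had no value. Genes were called at 2-fold, a size set beforehand. A list's median was placed among those of 10000 random lists of the same size, drawn from 20 bins of mean expression, as a description of these arrays.

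The genes named were chosen by a rule set before the data were examined. It took the 12 largest differences per direction among genes measured on all arrays compared, the 5 brightest bounds per direction of at least 2-fold, the members of 23 lists with the largest differences, and 13 pathway genes whatever their values, of which 1 is not reported here. The lists covered receptor and JAK-STAT genes, negative regulators, IRFs, both MHC classes, interferon-inducible GTPases, chemokines, checkpoint genes, antiviral genes, cell death, NF-κB and cytokines, tryptophan, arginine and nitric oxide metabolism, cell cycle, p53 targets, stress response, cholesterol synthesis, hypoxia and glycolysis, housekeeping genes, and markers of mesothelial, lung epithelial, mesenchymal, leukocyte and endothelial cells. Of their 519 entries, 505 had a named probe.

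On simulated arrays built from the real ones, the calls recovered 90.9% of 66 genes set to 2.83-fold and 89.4% of 66 set to 8-fold in AB1-HA (12944 genes run), and 95.5% and 98.5% in LLC (13284 genes run), with no calls at 1.5-fold or among genes left as they were. In each line, both simulated arrays were drawn from the vehicle array with repeat-spot noise, plus a constant shift on 1 of them. Spot noise of that size could hardly reach 2-fold, so the lack of false calls does not cover culture, labelling or signal-dependent differences. The alternatives tried were scaling to the array median, quantile and cyclic loess normalization, normexp background correction, the authors' value table, a stricter background filter (genes measured on every array compared) and none, the mean over a gene's probes, and saturated spots left out or outlier spots kept. Normexp had been planned on mean spot signals, a column not used here, and was run with offset 50 on median spot signals in its place, a choice made after the data were seen. All 4 arrays share 1 slide, so slide did not differ between groups. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used, and R 4.3.3 with limma 3.58.1 for normexp, quantile and loess steps.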

Results

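Messenger RNA signals were measured across the mouse genome in 2 tumor cell lines, AB1-HA and LLC, each cultured for 24 h with vehicle or with interferon gamma (IFN-γ), the cytokine through which activated T cells and natural killer cells raise antigen presentation and antimicrobial defence in other cells. AB1-HA is a mesothelioma line of BALB/c origin that carries influenza hemagglutinin as a model antigen, and LLC (also labelled 3LL) is the Lewis lung carcinoma line of C57BL/6 mice. By its title, the series looked for a regulator that holds back the genes IFN-γ induces in tumor cells. Each of the 4 groups held 1 array, so there were no replicates, the differences below have no replicate check, and the number of arrays limits their precision. On each array, between 22664 and 22947 of 39429 gene probes were well above background (57.5% to 58.2%), and no spot was saturated. The SD of the difference between 2 arrays among repeat spots of the same probe had a median of 0.062 in AB1-HA and 0.041 in LLC on the log2 scale, which covers spot noise on a single slide and neither culture nor labelling.

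Differences are given on the log2 scale or as folds, and a gene counted as higher or lower at a difference of at least 2-fold, a threshold of size and not of significance. A gene that was not well above background on 1 of the arrays compared has a bound, given as "at least". Genes with near-identical copies (the H2, Gbp, Tgtp, Irgm, Oas, Ifit, Apol9, Rhox2, Ifi20x, Olfr and H60 families) are uncertain for cross-hybridisation.

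The first comparison asked which genes differed after 24 h of IFN-γ in AB1-HA. The largest gains lay in the interferon-inducible GTPases, which attack intracellular pathogens: Gbp2 was 1082-fold higher on the IFN-γ array, Tgtp2 510.2-fold, Igtp 374-fold and Irgm2 234-fold, and Gbp4 at least 1901-fold. Cd274, which encodes the checkpoint ligand PD-L1, was 194-fold higher, and Cxcl9, a chemokine that draws CXCR3-bearing T cells, at least 222-fold. Among the genes lower on the IFN-γ array, Npnt (the integrin ligand nephronectin) was 5.81-fold lower, the alarmin Il33 4.97-fold, Dusp5 (a phosphatase that acts on ERK) 4.27-fold and the EGFR ligand Areg 3.60-fold. Of 13263 genes with a value, 395 were at least 2-fold higher on the IFN-γ array and 154 at least 2-fold lower. At the 4-fold level these counts were 214 and 10, and 74 genes were at least 16-fold higher.

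The other genes with the largest gains in AB1-HA were Gbp2b (9.58), Gbp3 (8.10), Gbp5 (7.98), the transcription factor Batf2 (7.53), Iigp1 (7.45), the ADP-ribosyltransferase Parp14 (6.64) and Gbp6 (6.40), all as log2 differences. Bounds of at least 449-fold, 352-fold and 96.5-fold were found for Mpeg1 (the pore-forming protein perforin-2), Gbp7 and Tgtp1. Toward the lower side, Dynap (−2.40), Ncmap (−2.34), the keratin Krt12 (−2.33), H60b, a ligand of the natural killer receptor NKG2D (−2.10), Rcan2 (−1.90), Sh2d1b1 (−1.89), Dmp1 (−1.88) and Mirt1 (−1.86) followed. Krt8, a keratin of simple epithelia, was at least 6.49-fold lower, and Rpe65, Calcb, Gsta2 and Ccdc121 were lower by bounds of at least 4.79-fold, 4.75-fold, 3.91-fold and 3.62-fold.

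Grouped by the lists fixed beforehand, receptor and kinase genes differed by little in AB1-HA, while Stat2, Stat3, IRFs and interferon target genes were higher. The higher genes in the list of receptor and JAK-STAT genes included Stat2 (3.82), Irf9 (2.53) and Stat3 (2.16), with a list median of 0.51 (0.27 over genes measured on both arrays). The receptor genes Ifngr1 (−0.02) and Ifngr2 (−0.16) and the kinases Jak1 (−0.02) and Jak2 (0.51) stayed within 2-fold. Among negative regulators of cytokine signalling, 5 of 28 were higher: the ISG15 protease Usp18 (4.02), the JAK inhibitor Socs1 (2.67), the RNA editor Adar (2.16, with 0.81 by another probe), Nfkbiz (1.45) and Zfp36 (1.25), with a median of 0.02 over the list. Of the 9 IRF-family and related regulators with a value, 6 were higher (median 2.70), with Irf1 at 4.44 and the MHC class I activator Nlrc5 at 5.63 (3.30 by another probe). The IRF median fell as low as 1.91 under the alternatives tried.

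Antigen presentation followed the same direction in AB1-HA. For MHC class I presentation, 22 of 27 genes were higher with a list median of 2.52, from B2m (1.63) to the immunoproteasome subunit Psmb9 (6.09), while the chaperones Calr (0.17), Canx (−0.06) and Pdia3 (0.07) stayed within 2-fold. For MHC class II, 6 of 9 were higher (median 2.18), among them the invariant chain Cd74 (4.38), H2-Eb1 (3.65) and H2-DMb1 (at least 42.7-fold), whereas Ciita, the class II transactivator, was not well above background on any of the 4 arrays. Normexp background correction left 4 MHC class II genes higher and lowered the median to 0.74. All 18 interferon-inducible GTPases were higher (median 7.66), and so were 34 of 40 antiviral interferon-stimulated genes (median 3.17), such as Ifit3 (5.07) and Ifi44 (5.03). Over all alternatives tried the GTPase median fell as low as 5.13, and over the other scalings alone as low as 7.57. The medians of the lists for JAK-STAT signalling, IRFs, both MHC classes, GTPases, antiviral genes and cell death lay above those of all 10000 random lists of the same size and mean expression.

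Immune-ligand and effector genes of AB1-HA were more mixed. Of 14 chemokines, 5 were higher (median 0.44, a value that fell to 0.23 with 3 higher under normexp, to 0.02 over genes measured on both arrays and to −0.20 without a background filter), including Cxcl10 (3.62) and Ccl2 (2.76), while Ccl5 was at −0.03 (a sign that turned under cyclic loess). Of 16 checkpoint and ligand genes, 4 were higher, with Ido1, the enzyme that starts tryptophan breakdown, at least 49.5-fold and Lgals9 at 1.64, and 2 were lower, H60b and Pdcd1lg2 (at least 2.11-fold). Tnfrsf14 was not counted as higher (0.08), but another of its probes had a bound of at least 3.95. Cell death genes were higher in 10 of 28 cases, among them Casp1 (2.33), Fas (2.55), Xaf1 (4.73) and Tnfsf10, which encodes TRAIL (at least 29.1-fold). For NF-κB and inflammatory cytokine genes, 4 of 21 were higher (Il18bp, the decoy for IL-18, at 4.35) and Il33 was lower. Il15ra was not counted as higher (0.19), but another of its probes had a bound of at least 4.79. In tryptophan, arginine and nitric oxide metabolism, 4 of 11 were higher, with Acod1 at least 55.8-fold and the tryptophanyl-tRNA synthetase Wars at 2.73. The list medians were 0.08 for checkpoint genes, 0.47 for cell death, 0.22 for NF-κB and cytokine genes and 0.07 for tryptophan metabolism, and the percentiles among random lists were 99.99 for chemokines and for NF-κB, 98.1 for checkpoint genes, 97.49 for negative regulators and 96.4 for tryptophan metabolism. Without a background filter the checkpoint and tryptophan medians also turned sign (−0.17 and −0.07).

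Growth and metabolic groups differed little in AB1-HA. None of 30 cell cycle genes and none of 21 p53 target genes passed 2-fold, with medians of −0.12 and −0.07 (percentiles 21.0 and 50.4). Of 20 stress response genes, 1 was higher (Atf3, 1.55; list median 0.10). Cholesterol synthesis showed a small gain shared across the pathway: 20 of 21 genes lay above 0, with a median of 0.38, above all 10000 random lists, with Mvd (0.62), Hmgcs1 (0.53) and Fdft1 (0.51) at its top, although none reached 2-fold. Hypoxia and glycolysis genes had a median of 0.09 with none past 2-fold, and this median and that of stress response genes also lay above all 10000 random lists. Mesothelial markers had a median of −0.29 over 9 genes (percentile 0.82), with the keratins Krt8 and Krt18 (−1.52) lower, though under normexp the median was −0.10 and neither keratin passed 2-fold. Lung epithelial (−0.07 over 9), mesenchymal (−0.02 over 16), leukocyte (−0.02 over 8), endothelial (0.06 over 6) and housekeeping (−0.05 over 18) medians were all near 0, and the signs for all of these but the endothelial list turned under at least 1 other scaling, and that of the endothelial list did without a background filter. Acta2 (1.28) was the mesenchymal gene past 2-fold, but not under normexp.

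The second comparison put the same question to LLC. Gbp2 was 2526-fold higher on the IFN-γ array, Tgtp2 3116-fold and Batf2 2959-fold, and Gbp3 and Gbp4 were at least 5956-fold and 3219-fold higher. The chemokines Cxcl10 and Ccl5, which recruit T cells, were 363-fold and 144-fold higher, and Zbp1, a sensor of Z-form nucleic acids that can start necroptosis, at least 1335-fold. On the lower side, Mogat2, an acyltransferase of triglyceride synthesis, was 5.54-fold lower, the matrix protein Dpt 4.21-fold, and the Wnt antagonist Dkk1 at least 8.15-fold. Of 13441 genes with a value, 494 were at least 2-fold higher and 196 at least 2-fold lower, or 193 and 10 at the 4-fold level, and 74 genes were at least 16-fold higher.

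The list of largest gains in LLC continued with Ifi47 (9.19), Igtp (8.35), Irgm2 (7.87), Apol9b (7.62), Iigp1 (7.54), Apol9a (7.22) and the pro-apoptotic Xaf1 (6.85), with bounds of at least 818-fold for Gbp7 and 807-fold for Oasl2. Lower genes included Gzme (−2.04), the acetylcholine receptor subunit Chrnd (−2.02), Chst8 (−1.97), Ggt1 (−1.95), Tspan2 (−1.94), the adhesion scaffold Nedd9 (−1.92), Lrrc15 (−1.81), Hrct1 (−1.79), the chemokine Ppbp (−1.77) and Fmo4 (−1.76). Chrnd and Fmo4 turned sign under normexp background correction (0.22 and 0.43). Pi16, Gal3st1, P2ry14 and C1qtnf7 were lower by bounds of at least 6.19-fold, 5.24-fold, 4.67-fold and 4.46-fold.

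In LLC, the higher receptor and JAK-STAT genes included Irf9 (3.23), Stat2 (3.13) and Stat3 (1.67) (list median 0.46, or 0.17 over genes measured on both arrays), with Ifngr1 at −0.41, Ifngr2 at −0.29, Jak1 at −0.17 and Jak2 at 0.46. The 5 of 28 negative regulators that were higher were Usp18 (4.31), Socs1 (2.49), Zfp36 (1.82), Adar (1.77, with 0.84 by another probe) and Nfkbiz (1.05, short of 2-fold under array median, quantile and loess scaling), and 3 stayed past 2-fold under normexp. Of 10 IRF-family and related regulators, 7 were higher (median 2.63, or 1.73 under normexp), with Irf1 at 4.43, Nlrc5 at 4.50 (2.30 by another probe) and Irf7 at least 37.4-fold. MHC class I genes were higher in 22 of 26 cases (median 2.73), from H2-T24 (1.18, and 0.99 under quantile and loess scaling) and B2m (1.64) to Psmb8 (6.35) and Psmb9 (6.55). For MHC class II, 3 of 9 were higher (median 0.68): Cd74 (2.08), H2-Ab1 (at least 11.1-fold) and Ctss (at least 2.76-fold). None of the 3 stayed past 2-fold under normexp, where the median was 0.41.

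Among the interferon-inducible GTPases, 17 of 18 were higher in LLC (median 8.06), all but Gbp2b (0.64). Over all alternatives tried this median fell as low as 5.83, and over the other scalings alone as low as 7.91. Antiviral genes were higher in 33 of 40 cases (median 2.72, as low as 1.97 under the alternatives tried), including Oas1a (6.46), Rtp4 (6.44) and Isg15 (5.08). Of 13 chemokines, 7 were higher (median 1.14, or 0.74 without a background filter), among them Cxcl9 at least 194-fold, Ccl2 (2.15) and Cxcl1 (1.66). Of 17 checkpoint and ligand genes, 4 were higher: Cd274 (5.59), Ido2 (3.20), Nt5e, which makes adenosine (1.71), and Tnfrsf14 (2.15-fold, but under 2-fold with the same 3 scalings, and at least 3.20 on the log2 scale by another probe), while Ido1 had a bound of at least 1.81-fold, short of 2-fold. Cell death genes were higher in 11 of 29 cases, with Casp1 (3.33) and Casp4 (3.18) among them. Of 21 NF-κB and cytokine genes 3 (Il18bp 4.82) were higher, and 3 of 11 genes of tryptophan, arginine and nitric oxide metabolism (Acod1 at least 14.3-fold, Nos2 1.90) were as well. Il15ra was not counted as higher (0.87), but was at 3.59 by another probe. Medians were 0.30 for checkpoint genes, 0.36 for cell death, 0.38 for NF-κB and cytokine genes and 0.49 for tryptophan metabolism. The first 3 fell to 0.15, 0.21 and 0.24 under array median scaling, and the last to 0.14 over genes measured on both arrays. The medians of all these lists in LLC, except those of negative regulators (median −0.02, percentile 76.2), MHC class II, checkpoint and tryptophan genes (percentiles 99.9, 99.6 and 99.9), lay above those of all 10000 random lists.

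Of 30 cell cycle genes in LLC, 2 were higher (Aurkb 1.49, and Ccne2 by a bound of at least 2.98-fold), with a median of −0.08 (percentile 12.8), and neither passed 2-fold under normexp. None of 21 p53 target genes passed 2-fold (median −0.12, percentile 26.7), and Atf3 (1.87) alone among 20 stress response genes did (list median 0.15, percentile 99.4). Cholesterol synthesis genes had a median of −0.16, with 16 of 20 below 0 and none past 2-fold, at percentile 4.7 of random lists. Hypoxia and glycolysis genes had a median of −0.11 (percentile 2.48) with none past 2-fold. Mesenchymal markers had a median of −0.14 over 15 genes (percentile 14.8) and 3 lower members, Col1a1 (at least 3.74-fold), Pdgfrb (−1.12, with 0.29 under normexp) and Col3a1 (−1.04). Among mesothelial markers (median −0.35 over 10, percentile 0.46), the surface antigen Msln (−1.43) was lower, though within 2-fold under normexp, and lung epithelial markers had a median of −0.42 over 11 (percentile 1.04). Both medians turned sign without a background filter (0.22 and 0.24), and the lung epithelial median was −0.03 under normexp. Leukocyte markers had a median of 0.21 over 9 (percentile 94.0; 0.07 under array median scaling) with Csf1r higher (1.74, but 0.28 by another probe), and endothelial and housekeeping medians were 0.05 over 6 and 0.02 over 18, signs that turned under other scalings. Scaling to the array median in place of the 75th percentile gave 325 lower genes in LLC and a 55.5% share of higher genes among those past 2-fold, against 196 and 71.6% here. Quantile and cyclic loess normalization gave shares of 60.5% and 55.7%. Under the other scalings, LLC medians fell as low as −0.22 for cell cycle, −0.26 for p53 target and 0.003 for stress response genes. For cholesterol synthesis, for hypoxia and glycolysis and for mesenchymal genes the lows were −0.31, −0.25 and −0.28.

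**Figure D1:**
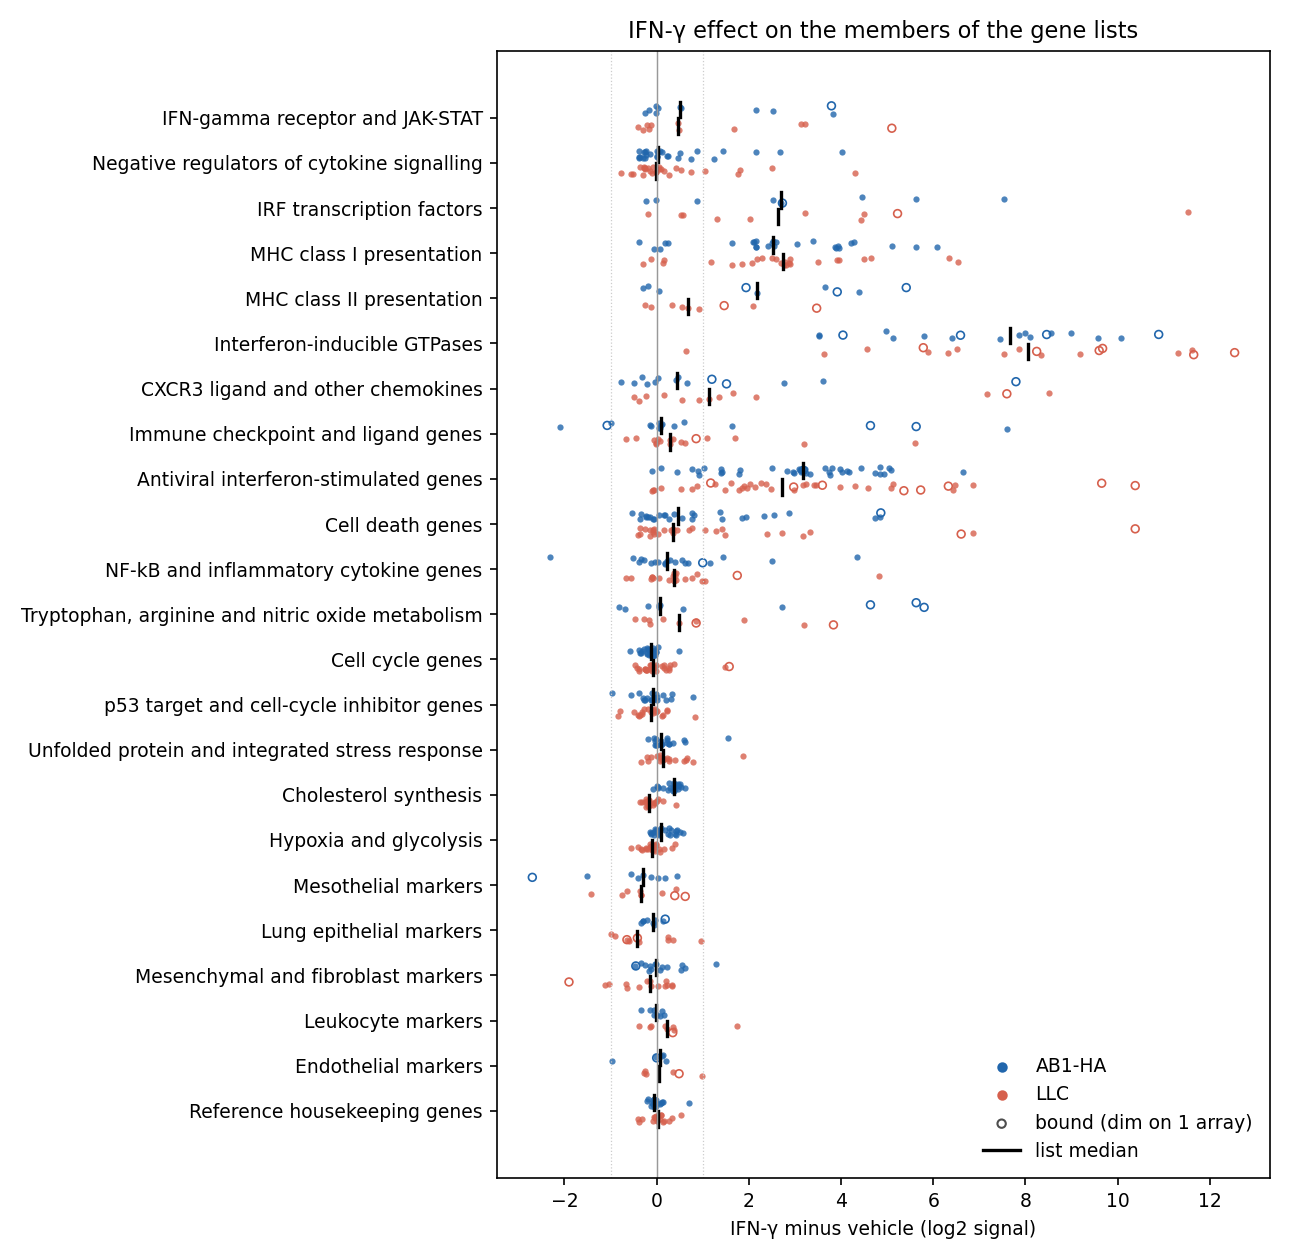
Log2 difference between the IFN-γ and the vehicle array (x axis) for each member of the 23 gene lists (y axis), in AB1-HA (blue) and LLC (red). Filled points are measured on both arrays, open points are bounds for genes not well above background on 1 of them, and black bars are list medians; the GTPase medians lie at 7.66 and 8.06, and those of cell cycle genes at −0.12 and −0.08.

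The third comparison set the IFN-γ effects of the 2 lines against each other. The shared core was large: Irf1 (4.44 in AB1-HA and 4.43 in LLC), B2m (1.63 and 1.64), Socs1 (2.67 and 2.49), Igtp (8.55 and 8.35) and Irgm2 (7.87 and 7.87) differed between the lines by less than 2-fold. Ccl5 had the effect furthest toward LLC, with a difference of effects of 7.19, followed by Cxcl10 (4.89), Ifi47 (4.22), the activin antagonist Fst (4.22) and Batf2 (from 7.53 in AB1-HA to 11.53 in LLC). Gbp2b lay furthest toward AB1-HA at −8.94 (its other probe was 10.96 higher in AB1-HA and not well above background on either LLC array), followed by the MHC class II chain H2-Eb1 (−3.32) and Phf11b (−3.20). The gain of Cd274 was also greater in AB1-HA (−2.01), where its vehicle signal was dimmer than in LLC. Among 12516 genes with a value in both lines, 232 were higher in both, where independent calls (335 in AB1-HA, 439 in LLC) would share 11.8. For lower genes, 5 were shared (89 and 104 called), where independence gives 0.74.

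Among genes measured on all 4 arrays, each of the 12 whose effect was furthest toward LLC was dimmer with vehicle in LLC than in AB1-HA. These vehicle differences ran from −0.47 for H2-Q8 to −7.72 for Oas1a. Cxcl10 differed by −5.43 between the vehicle arrays (LLC minus AB1-HA) and by −0.55 between the IFN-γ arrays, and Ifi47 by −5.07 and −0.85. Ccl5 differed by −6.11 with vehicle and 1.08 with IFN-γ, Fst by −5.54 and −1.31, and Oas1a by −7.72 and −4.24. The same vehicle arrays enter both quantities, so the difference of effects and the vehicle difference are not independent. The remaining genes furthest toward LLC were Apol9b (3.63), Oas1a (3.48), Cfap45 (3.48), H2-Q8 (3.43), Apol9a (3.38), the steroid reductase Akr1c18 (2.99) and Rprl2 (2.89). Toward AB1-HA they were Septin4 (−2.84, with 0.15 under normexp background correction), Asap3 (−2.78), the iron regulator Hfe (−2.75), Pcbp3 (−2.70), H2-T24 (−2.69), the lipopeptide receptor Tlr2 (−2.60), Neurl3 (−2.37), Mlph (−2.33) and Icam2 (−2.31).

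By list, the difference of effects leaned toward AB1-HA for MHC class II (median −0.72 over 6 genes, percentile 0.01, but −0.18 under normexp, with Cd74 at −2.30), for cholesterol synthesis (−0.44 over 20, below all 10000 random lists), for mesenchymal markers (−0.34 over 14, percentile 0.02, but −0.05 without a background filter), for antiviral genes (−0.28 over 32, percentile 0.01, with 7 greater in AB1-HA, such as Ifit3 at −1.89, and 5 in LLC) and for hypoxia and glycolysis (−0.22 over 23, below all 10000 random lists). It leaned toward LLC for chemokines (0.49 over 9, percentile 99.5) and for NF-κB and cytokine genes (0.22 over 18, percentile 98.3, but 0.08 under array median scaling). The antiviral and hypoxia medians were −0.42 and −0.41 under cyclic loess, and the antiviral median −0.18 without a background filter. In LLC, 8 antiviral genes had only bounds and could not enter the difference of effects. They included Ifih1 and, by the probe used, Zbp1, whose gains were larger in LLC than in AB1-HA. The bound of Oasl2 in LLC also exceeded the largest antiviral value in AB1-HA (6.64). The direction of the others was not counted. The antiviral lean toward AB1-HA therefore holds only for the 32 genes measured on every array. Likewise, the MHC class II lean covers only 6 of the 14 class II genes named on the array. H2-Ab1 could not enter it, with bounds of at least 1.94 in AB1-HA and at least 3.47 in LLC, which leave its direction unknown. Medians were −0.08 for MHC class I (percentile 1.90), −0.14 for receptor and JAK-STAT genes, −0.08 for negative regulators and −0.05 for p53 targets (percentiles 11.2, 8.35 and 25.6), with no gene past 2-fold except in MHC class I (3 greater in AB1-HA, 1 in LLC; 1 and 0 under normexp). The medians of GTPases (0.11), IRFs (0.04), checkpoint genes (0.06), cell death (0.06), tryptophan metabolism (0.00), cell cycle (0.07), stress response (0.04), mesothelial (0.01), lung epithelial (0.14), leukocyte (0.28) and housekeeping genes (0.07) turned sign under at least 1 other scaling, and the endothelial median was 0.21 (0.07 under array median scaling).

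Across the 12002 genes well above background on all 4 arrays, the effects in the 2 lines had a Pearson r of 0.63 and a Spearman rho of 0.14, and over the 11460 genes under 2-fold in both lines 0.11 and 0.08. These are correlations across genes, which are not independent replicates. Of the 172 genes higher in both lines and measured on all 4 arrays, 27 had an effect at least 2-fold greater in LLC and 31 in AB1-HA. Over all 12002 genes, 305 were at least 2-fold greater in LLC and 203 in AB1-HA, a 60.04% share in LLC that was 39.9% with array median scaling, 47.9% with quantile normalization and 36.0% with cyclic loess. Which line held more of these genes therefore depended on the scaling. Cyclic loess gave 182 genes greater in LLC and 323 in AB1-HA, and array median scaling gave 319 in AB1-HA.

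**Figure D2:**
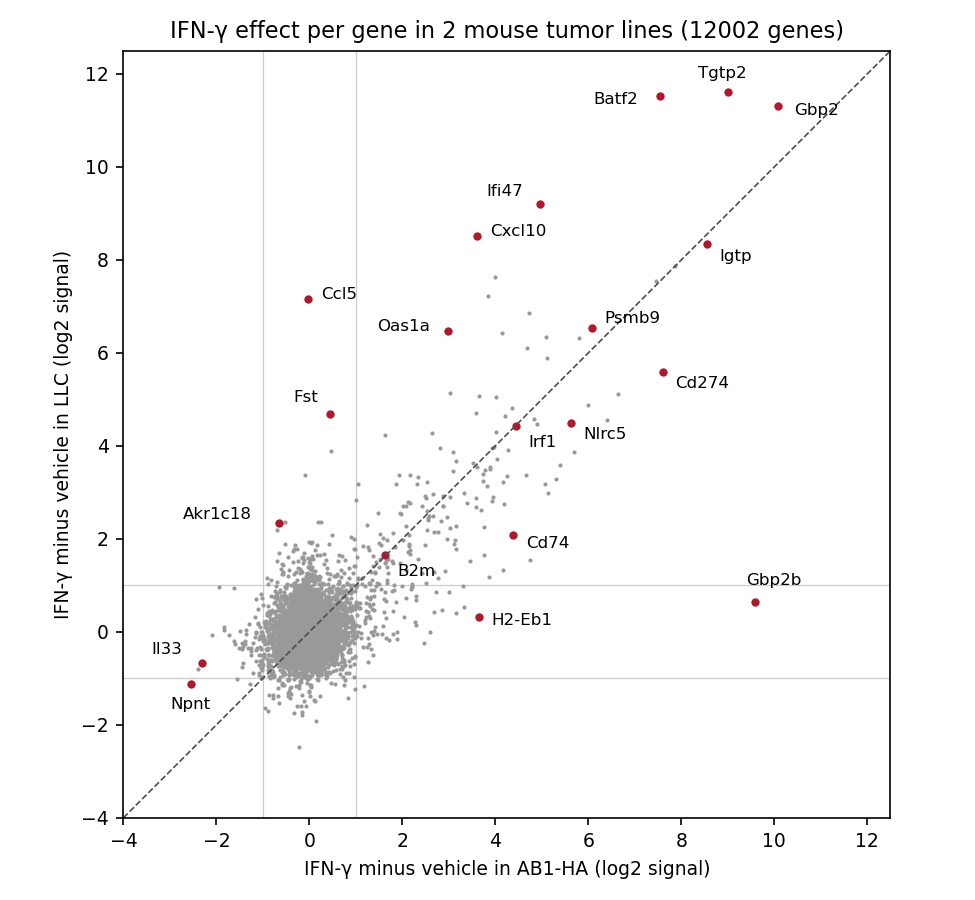
Log2 difference between the IFN-γ and the vehicle array in AB1-HA (x axis) and in LLC (y axis) for 12002 genes well above background on all 4 arrays; each point is a gene, the dashed line marks equal effects and grey lines mark 2-fold. Ccl5 lies at −0.03 and 7.17, Gbp2b at 9.58 and 0.64, and Irf1 on the line at 4.44 and 4.43.

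The last comparison set the 2 lines against each other with vehicle. LLC was brighter for the X-linked homeobox genes Rhox2h (4681-fold) and Rhox2e (2107-fold), for the keratins Krt18 (485-fold) and Krt8 (172-fold) and for the receptor tyrosine kinase Fgfr1 (8.23 on the log2 scale by the probe used, and 7.57 and 0.48 by 2 others, so its size depends on the probe). AB1-HA was brighter for the collagen genes Col1a2 (4164-fold) and Col1a1 (462-fold), for the matrix genes Sparcl1 (2539-fold) and Mgp (996-fold), and for the mesothelioma antigen Msln (378-fold). AB1-HA was also brighter for antiviral genes without added IFN-γ: Oas1a was 210.4-fold and Oasl1 344-fold higher there, and Zbp1 at least 313-fold. Another Zbp1 probe gave a bound of −0.99 on the log2 scale and an IFN-γ difference of 8.84 in AB1-HA, against 4.84 by the probe used, so the level of Zbp1 with vehicle depends on the probe. Of 13885 genes with a value, 2277 were at least 2-fold higher in LLC and 2218 in AB1-HA. The lines differ in strain, tissue of origin and culture history, which this comparison cannot separate.

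Further genes brighter in LLC were the phosphatase gene Dusp2 (10.14), Ydjc (9.72), Tbkbp1 (9.41), Spink2 (8.88), Pcbp3 (8.83), the laminin receptor Itga7 (8.13), Camk1d (8.04) and Acsf3 (8.01), with bounds of at least 6109-fold for Rhox2c, 3126-fold for the retinol carrier Rbp4, 1962-fold for Fabp5, 1875-fold for Egfl7 and 1688-fold for the matrix protease Mmp3. Further genes brighter in AB1-HA were Slc16a11 (−10.87), Olfr1221 (−10.67), Chil3 (−10.48), Cdhr5 (−9.36), Pianp (−9.16), Ifi27l2a (−9.07), Wfdc3 (−9.05) and Tmem171 (−8.70), with bounds of at least 6687-fold for Stmn2, 2737-fold for Ifi202b, 2467-fold for Itgbl1, 2089-fold for Ggh and 1924-fold for Hoxd13.

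Of 39 antiviral interferon-stimulated genes, 22 were lower and 3 higher in LLC with vehicle (median −1.57, below all 10000 random lists, and −0.84 over genes measured on both arrays), among them Isg15 (−3.84), Usp18 (−4.03) and Trim30a (−4.23). Of 27 MHC class I genes, 10 were lower and 2 higher (median −0.51, percentile 0.84), and 6 of 15 GTPases were lower and 1 higher (−0.55, percentile 2.66; 4 and 0 under normexp). The higher GTPase was Gbp6, at 1.54 by the probe used, while its other probe gave a bound of −2.55. Cell death genes had a median of −0.39 (percentile 2.70; −0.20 under cyclic loess) with 9 of 28 lower and 2 higher, the lower ones including Casp1 (−4.66) and the necroptosis kinase Ripk3 (−6.19). Cholesterol synthesis genes were dimmer in LLC as a group (median −0.85 over 21, below all 10000 random lists), with Insig1 at −1.69. Mesothelial markers went both ways (median −0.94 over 10, percentile 0.62, with −0.29 without a background filter and −1.59 over genes measured on both arrays), with Msln and Pdpn (at least 1485-fold) brighter in AB1-HA and Krt8 and Krt18 in LLC.

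Receptor and JAK-STAT genes had a median of 0.55 over 10, with Ifngr1 at 0.46, Ifngr2 at 0.64, Jak1 at 0.64 and Jak2 at 0.02. For the other lists the vehicle medians were 0.24 for negative regulators, 0.09 for IRFs, 0.69 for MHC class II, −0.31 for chemokines (Cxcl10 −5.43, Ccl2 6.20), 0.29 for checkpoint genes (Cd274 2.22), 0.08 for NF-κB and cytokine genes, 0.08 for p53 targets, 0.05 for stress response, 0.08 for lung epithelial, 0.21 for mesenchymal, −0.51 for leukocyte and −0.50 for endothelial genes. Medians of −0.03 for tryptophan metabolism, −0.11 for cell cycle, −0.08 for hypoxia and −0.10 for housekeeping genes turned sign under at least 1 other scaling. Without a background filter so did those of IRFs (−0.15), MHC class II (−0.23), checkpoint (−0.28), NF-κB (−0.12), lung epithelial (−0.25) and mesenchymal genes (−0.13), and over genes measured on both arrays those of checkpoint (−0.41) and lung epithelial genes (−0.30), while the chemokine median was −1.0 there. The endothelial and leukocyte medians fell to −0.05 under normexp and −0.22 in the authors' value table. The percentiles of the lists in this paragraph ran from 15.06 to 96.31.

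**Figure D3:**
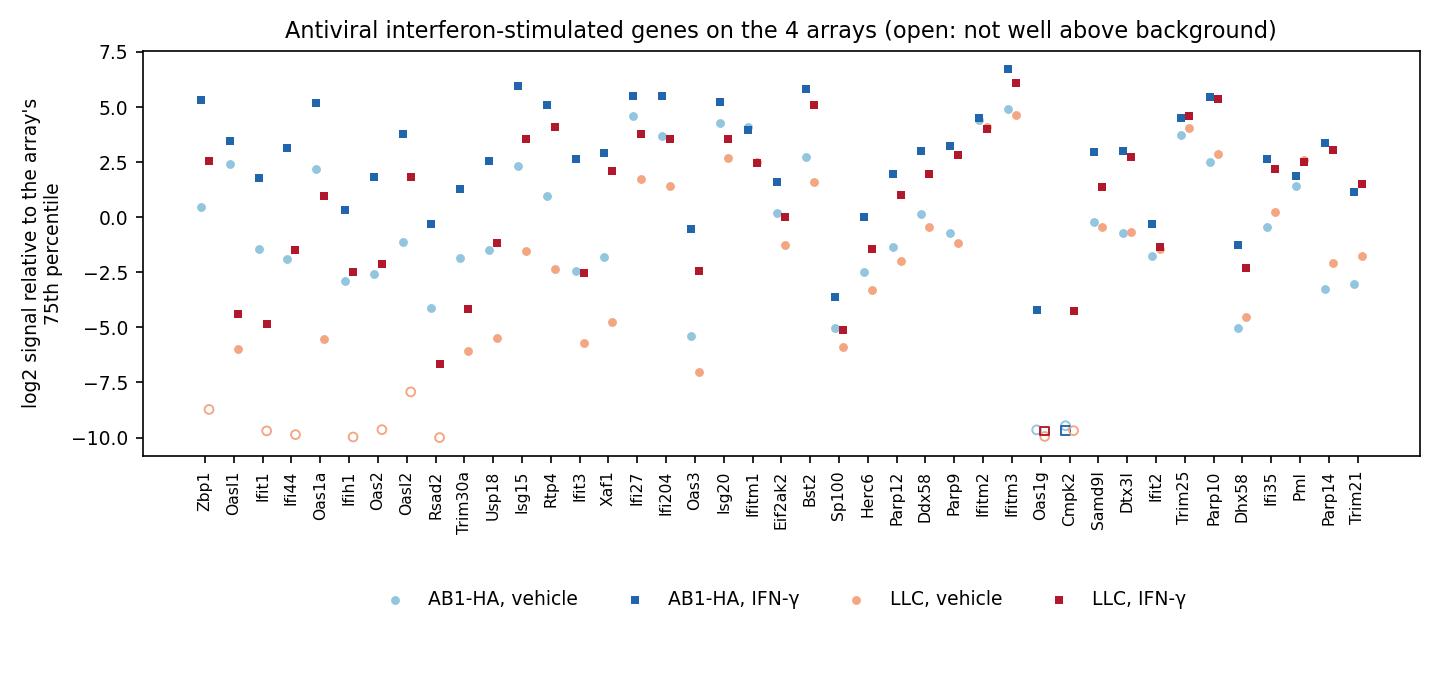
Log2 signal relative to the array's 75th percentile (y axis) of 41 antiviral interferon-stimulated genes (x axis, ordered by the vehicle difference between the lines) on the 4 arrays; circles are vehicle, squares IFN-γ, blue AB1-HA and red LLC, and open symbols are not well above background. Genes such as Oasl1 and Oas1a, at the left, were far dimmer with vehicle in LLC than in AB1-HA, by 344-fold and by 210.4-fold.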

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

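The tests of a signal-dependent difference and of a constant offset in this part were chosen after the results had been seen. With 1 array per group no array could be compared with others of its group. The differences between the lines given here were not tested. Akr1c18 was lower with IFN-γ in AB1-HA (−0.65) and higher in LLC (2.34), a difference of effects of 2.99. Rprl2 went the same ways, −0.53 and 2.36, a difference of 2.89. Mlph, which links melanosomes to a motor protein, was higher in AB1-HA (1.17) and lower in LLC (−1.16), a difference of −2.33. Pdgfrb, a growth factor receptor of mesenchymal cells, was at 0.55 in AB1-HA and −1.12 in LLC, a difference of −1.67, and its LLC value was 0.29 under normexp background correction. The cholesterol synthesis list had medians of opposite sign, 0.38 in AB1-HA and −0.16 in LLC, which lie −0.54 apart. The LLC median was at percentile 4.7 of random lists. Those lists had a median of −0.06, as did all measured LLC genes, so the lowering in LLC was small.

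Signal also appeared in probes without a gene name, which no comparison used. Of these, 165 were at least 2-fold higher with IFN-γ in AB1-HA (71 lower) and 358 in LLC (48 lower).

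Named genes showed the same lean, with 494 higher in LLC against 395 in AB1-HA, and the excess lay in small gains. Between 2-fold and 4-fold, 301 genes were higher in LLC and 181 in AB1-HA, whereas 193 and 214 passed 4-fold. Among the 12002 genes measured on all 4 arrays, in the dimmest of 3 equal classes of brightness, 136 and 65 genes were 2-fold to 4-fold higher, in the middle class 47 and 29, and in the brightest 19 and 23. A signal-dependent difference between the LLC arrays is a candidate explanation: cyclic loess normalization, which removes such a trend, left 411 genes higher in LLC and 439 in AB1-HA. A constant offset in the scaling is another candidate. Array median scaling, which shifts all genes of an array alike, left 405 and 391, so these counts favour neither. Any downward shift of the LLC differences lowers the LLC count, so the drop by itself is no evidence of an offset. The same scaling moved the median LLC difference from −0.06 to −0.20 and gave 325 lower genes in LLC against 196. A weak gain of many genes that is real in LLC stays open, since cyclic loess and array median scaling would both remove part of it too.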

How the results depend on the processing

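The alternatives were set before the data were examined, except normexp on median spot signals. A model of treatment with line as a block was not run, and with 1 array per group none was left out in turn. Quantile normalization, the authors' value table, the stricter background filter, the mean over a gene's probes and kept outlier spots left the counts of called genes in each comparison within 1.5 times (counts within gene lists changed more), and leaving out saturated spots removed nothing since there were none. Of 549 genes past 2-fold in AB1-HA, 498 (cyclic loess) to 545 (array median) were also past it under array median, quantile and loess scaling, and of 690 in LLC, 601 to 617. Array median scaling gave 325 lower genes in LLC and 319 genes greater in AB1-HA. Cyclic loess gave 327 lower in LLC, with 182 genes greater in LLC and 323 in AB1-HA. The median difference of all LLC genes shifted by −0.14 under array median scaling, that of the difference of effects by −0.14 there and −0.12 under cyclic loess, and that of the vehicle arrays by 0.14 under cyclic loess; the cause was not tested.

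Normexp gave 259 higher and 20 lower genes in AB1-HA, 253 and 20 in LLC, 131 greater in LLC and 75 in AB1-HA, and 1496 and 1407 higher in LLC and AB1-HA with vehicle. Its offset of 50 exceeds the arrays' median signals (28.8 to 33.1), so dim genes' differences shrink by construction. Signs were checked for the genes named by the rule and the list members, not for all called genes. All 9 called values among them that turned sign did so under normexp. In LLC these were Chrnd 0.22, Fmo4 0.43, Npnt 0.23 and Pdgfrb 0.29. Between vehicle arrays they were Gbp6 −0.24, Mlph −0.055 and Pi16 −0.0043, and for the difference of effects Septin4 0.15 and Spink2 0.52. The cause was not tested for single genes.

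Without a background filter, 723 genes were higher and 589 lower in AB1-HA, 890 and 488 in LLC, and 1394 and 883 greater in LLC and AB1-HA, with a Pearson r of 0.47 and a Spearman rho of −0.0072. By construction this adds the genes near background, which is where signal limits these arrays. Among all repeat-printed probes, the median SD of a spot difference in AB1-HA was 0.203 in the dimmest of 3 brightness classes and 0.055 in the brightest. Among those well above background it was 0.096 and 0.055.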

Other observations

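All tests in this part were chosen after the results they concern had been seen, as were the 3 gene lists below, from which the genes with the largest differences and brightest bounds named by the fixed rule were left out of the medians. The lists also held 3 genes whose values had been seen before they were drawn up (Serping1, Spon2 and Prss23), and the matrix list held members of the fixed lists, such as Col3a1, so medians are given with and without them. The versions without them were added after the first had been computed, and the tests rest on the strictest. None of the 3 lists was rerun under the other scalings or normexp. Complement genes were higher with IFN-γ in both lines. Classical pathway components C4b (64.0-fold in AB1-HA and 29.5-fold in LLC), C2 (15.2-fold and 7.01-fold) and C1s1 (12.9-fold and 6.14-fold) led, the alternative pathway gene Cfb was at least 8.65-fold and 5.47-fold higher, and the C1 inhibitor Serping1 65.0-fold in AB1-HA and at least 3.17-fold in LLC, while C3 stayed at 0.22 and 0.47 on the log2 scale. In LLC, Cd59a was at −0.83. Over 11 genes the medians were 2.93 and 1.31, and over the 10 without Serping1 2.80 and 1.30, all at the 100th percentile of 10000 random lists, as a group that may respond together would show.

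EGFR ligands and ERK feedback genes leaned lower in AB1-HA: beside Areg and Dusp5, Ereg was at −1.17, Hbegf at −1.05, Egr1 at −0.83 and Spry4 at −0.75. Of 15 genes, 13 lay below 0 (Etv1 was at 0.33 and Dusp6 at 0.17), and their median of −0.30 was at the 0.04th percentile of random lists. In LLC, Egr1 was at 1.11 and Hbegf at 0.81, and the median over 17 genes was 0.02 (84.9th percentile). ERK activity itself was not measured. In LLC, collagen and matrix genes leaned lower, with Col6a1 at −1.37, Col6a2 at −1.27, Spon2 at −1.74 and Prss23 at −1.73, and Eln (by a bound of at least 0.75), Loxl2 (0.47), Fbn1 (0.27) and Col8a1 (0.16) higher. Of 17 genes, 13 lay below 0 and 5 passed 2-fold, and their median was −0.59, or −0.54 over the 15 without Spon2 and Prss23 and −0.47 over the 13 also without members of the fixed lists (9 below 0, 2 past 2-fold), all below all 10000 random lists (a percentile of 0). In AB1-HA these medians were −0.17 over 19 genes (percentile 5.54), −0.10 over 17 (percentile 29.1) and −0.10 over 15 (percentile 29.8).

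AB1-HA showed antiviral genes without added IFN-γ: 22 of the list were at least 2-fold brighter there with vehicle than in LLC, by a median of −3.78 (LLC minus AB1-HA). RNA of IFN-γ-treated cells in the vehicle sample is argued against, since the 14 GTPases measured on both arrays kept a median of 0.50% of their treated signal, where the antiviral genes kept 7.18%. Loss of these genes' probe sites in LLC is argued against by 20 of the 22 being at least 2-fold higher with IFN-γ in LLC, and scaling by the list median staying at −1.42 or below under every scaling tried. Sequence mismatch under some probes could not be told apart, since 9 of the 22 genes differed by a like factor on the IFN-γ arrays, where the median was −2.58. Tonic type I interferon signalling in AB1-HA, or a difference of strain or tissue, may underlie the rest and was not tested.

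Gbp2b was 9.58 higher with IFN-γ in AB1-HA and 0.64 in LLC. Cross-hybridisation from Gbp2, whose probe was brighter by 0.76 on the LLC than on the AB1-HA IFN-γ array, is argued against, as the LLC array kept 0.0268% of the AB1-HA signal of Gbp2b. A sequence difference under a single probe is argued against by the gene's other probe, which was 10.96 higher in AB1-HA and not well above background on either LLC array. A difference between BALB/c and C57BL/6 at the gene itself cannot be told apart from a difference between the cell lines, since there was 1 line per strain.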
